A study of Homo sapiens with 4 samples.

How the data were processed

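RNA was extracted with silica columns from MCF7 cells grown in RPMI 1640 medium with 10% fetal bovine serum, per the labels' protocols. The 4 samples fell into 2 groups by their labels, DMSO and NSC 59687, with 2 numbered replicates each. The labels give a dose of 10 µM and a time of 24 h for NSC 59687. Samples were labelled with biotin and hybridised 1 per array, so each array has 1 colour. The authors processed the arrays in Affymetrix Expression Console 1.3, per the submitters' processing notes. The summary algorithm, its settings and any background correction are not given in the sources used here. The deposited values are linear intensity, not log values, as the range from 0.0820 to 63951 shows. The mean of each array, leaving out the highest and lowest 2% of probe sets, was 500.1, so the authors scaled each array to a common mean. Such scaling fixes the average and can move many genes one way when bright genes change. The direction and log base of the values are not in doubt, because they are positive single-array intensities.

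Of 54675 probe sets, 62 were controls. The platform annotation used here gave exactly 1 gene symbol to 41091 of the others, several to 1801 and none to 11721. Symbols were checked through Entrez gene numbers in the RefSeq gene table of assembly GRCh38.p14, which matched 41037 of the single-symbol probe sets and changed 0 symbols. Probe sets with no symbol or several were left out of the gene test and were tested only together with all probe sets. For each gene the probe set with the highest mean over the 4 arrays was used, which gave 19775 genes, 10523 of them with more than 1 probe set. For 50 called genes another probe set was called the other way, and none of these was among the 134 genes named by the rule. Values were put on log2(value + 16) with no further normalization. Microarray probe sets with shared probes, 28.5% of those chosen to stand for a gene, can read related transcripts together.

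NSC 59687 was compared with DMSO in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with defaults, two-sided). Benjamini-Hochberg adjustment ran over all genes with a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot reach that threshold, so limma's moderated test, which borrows spread across genes, is the only one given. Its prior had 1.83 degrees of freedom beside 2 residual ones. The lowest adjusted p was 0.0177. Replicate numbers are shared between the groups, but the labels do not say that they mark a shared culture or day, so the fit had no replicate block.

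Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The 32 lists held 754 genes, of which 680 were measured. Each list was tested with camera at a preset correlation of 0.01 and adjusted over the lists. None of the 13 calls held with an estimated correlation. That setting also judges each list on the 2 residual degrees of freedom, so a call is hard to reach there. The p53 targets had an estimated correlation of 0.0119, near the preset one, yet their call was lost. For that list the loss therefore does not show that correlated members undo the call. Other called lists had higher estimated correlations, such as 0.184 for hypoxia and glycolysis, 0.139 for tRNA synthetases and 0.136 for G2/M genes. For these the setting cannot tell correlated members from few degrees of freedom. Fry was run beside camera. The named genes were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose higher group lay at or above the median gene. They also included up to 4 called members of each list with the largest changes, or up to 2 of its brightest members where none was called. CCND1, ATF4, DDIT3, ATF3, ASNS, CHAC1, TRIB3, TNF, SQSTM1 and ESR1 were always named.

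Alternatives were quantile normalization, median centring, leaving out genes below the median signal, trended and robust spread, the mean of probe sets, and leaving out probe sets with shared probes. Others were every probe set, a replicate block, each array left out, pseudocounts of 1 and 64, thresholds of 0.01 and 0.1, and limma's treat with a fold of 1.2. Lower bounds for folds against a group within the trpn control range, leaving out each array with trended spread, counts of list members without DMSO replicate 2, and 10000 random lists matched on mean signal in 20 bins were added after seeing the data.

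The tests were checked on simulated data drawn from the real gene means and residual spreads, with 200 of 19775 genes changed, all at or above the median signal. Over 10 draws in which the other genes changed as fitted, 89.8% of genes changed by 1 on the log2 scale were recovered, and 98.8% of those changed by 2. With no other gene changed, 0% and 10% were recovered, since the adjustment is harder to pass when few genes change. In 10 draws with no change, 0 genes and 0 lists were called. A list shifted by 1 was called in 10 of 10 draws. Smaller shifts were not simulated, although the median of ribosome biogenesis, a called list, differed from that of all genes by only −0.22. Simulated genes varied independently of each other, so these draws do not test lists whose members vary together. In the data the estimated correlation within a list reached 0.905, for cytosolic ribosomal proteins.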

Results

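MCF7 cells, an established human breast cancer line of luminal type that carries the estrogen receptor, were treated with 10 µM NSC 59687 for 24 h. NSC 59687 is oxyphenisatin acetate, a compound once used as a laxative. RNA was measured on 4 Affymetrix Human Genome U133 Plus 2.0 arrays, 2 from cells given the solvent DMSO and 2 from treated cells. The labels do not say that the replicates came from separate cultures. The p-values of single genes thus measure the spread between these arrays, which may be technical. Camera's p-values with the preset correlation compare genes in a list with other genes, so they mainly reflect spread across genes. A small value there does not stand for many replicates. With 2 arrays per group, the number of arrays limits the precision of every value.

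The deposited values were linear intensities with the same trimmed mean on each array, near 500.1. The median signal was 89.9 and 99.4 on the DMSO arrays and 68.1 and 72.2 on the NSC 59687 arrays. Across probe sets, log2 values correlated at 0.967 between the DMSO arrays and 0.978 between the NSC 59687 arrays. Between groups the correlations ran from 0.934 to 0.942. DMSO replicate 2 stood apart in its control probe sets. Its hybridisation controls were 2.28 times as bright as those of DMSO replicate 1. The ratio of 3′ to 5′ signal for beta-actin was 2.12 on that array, against 1.12 on DMSO replicate 1 and 1.38 and 1.17 on the NSC 59687 arrays. The same ratio for GAPDH lay between 0.965 and 1.03 on all 4 arrays.

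The single comparison asked which transcripts differed between treated cells and solvent controls. Among the transcripts with the largest rises were several known p53 targets. GADD45A, a DNA damage and growth arrest gene, rose from a signal of 184 ± 34.4 (SD, n = 2) to 5209 ± 239. FAS, a death receptor, rose from 233 ± 0.169 to 4483 ± 203, and CDKN1A, which encodes the cell cycle inhibitor p21, rose from 1171 ± 124 to 12317 ± 300.4. PGR, the progesterone receptor, fell from 3556 ± 358 to 400.0 ± 13.1, and MYC fell from 12728 ± 256 to 2197 ± 131.

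Of 19775 genes tested with limma, 4331 passed an adjusted p threshold of 0.05. Of these, 1402 rose and 2929 fell, which is 32.4% and 67.6%. At least 2-fold changes were called for 2765 genes, 791 upward and 1974 downward. The groups did not overlap for 65.6% of all genes, where chance alone gives 33.3%. The balance of rises and falls depended on how the arrays were scaled. Quantile normalization gave 1467 rises and 2085 falls, and centring each array on its median gave 2366 rises and 1306 falls. The median log2 fold change of all genes was −0.26 as deposited, −0.08 after quantile normalization and 0.10 after median centring. No gene called as deposited was called in the opposite direction under either other scaling.

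With 1 array left out and limma's default settings, 0 genes passed. These fits keep 1 residual degree of freedom and 1 array in an arm, so they say little about single genes. Unadjusted p-values under 0.05 were then found for 7212 genes without DMSO replicate 1, 6482 without DMSO replicate 2, 5368 without NSC 59687 replicate 1 and 5423 without NSC 59687 replicate 2. When the spread was allowed to follow the signal level, a setting chosen after seeing the data, the same 4 fits called 5985, 5490, 4252 and 4367 genes. Of the 4331 genes, 3699, 3616, 3411 and 3447 were also called there.

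The 12 largest fitted rises came from GPNMB, GADD45A, FAS, CYP1A1, GDF15, AP1S3, LIF, ANXA3, CDKN1A, MAFF, OVOL2 and TP53INP1. GPNMB, a transmembrane glycoprotein found in lysosomes and melanosomes, was at least 12.2-fold higher in treated cells (adjusted p = 0.0177). Its DMSO signals lay within the range of bacterial trpn control probe sets, taken over all 4 arrays. These should not hybridise and read up to 71.8, a value from DMSO replicate 2. A group in that range has only a bound, so its arrays were set to no less than 71.8 and the fold is given as at least that size. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, rose from 64.7 ± 35.0 to 997 ± 61.0, at least 10.5-fold, with 1 of 2 DMSO arrays in that range. The same held for LIF, a cytokine of the interleukin 6 family, at least 7.62-fold higher. GDF15, a stress-induced cytokine, rose by 3.61 ± 0.15 (SE) on the log2 scale. This value came from its brightest probe set, and with probe sets shared between transcripts left out, another probe set gave −1.03. The calls of FAS and OVOL2 ended in that setting, where their log2 fold changes of 4.18 and 3.26 became 0.65 and 0.19 through other probe sets. With every probe set tested, 4 of the 5 for FAS and 1 of the 2 for OVOL2 were called upward, and none downward. CDKN1A, MYC, SLC2A10 and EEF2KMT have only 1 probe set each, of the shared kind. They dropped out when shared probe sets were left out, so that setting did not test them. The call of LIF ended with a pseudocount of 1 although its fitted value did not shrink (adjusted p = 0.0503). The 12 largest fitted falls came from SLC2A10, EEF2KMT, TMPO-AS1, C9orf152, EFHD1, IFT70B, CBR4, ACOT4, LURAP1L, PRKAG2-AS1, SUSD3 and LOC101926959. In 8 of these 12 both treated arrays lay within the control range, so the order of the falls is not set. On the treated arrays themselves the trpn probe sets read at most 47.4 and 32.3, and SLC2A10, EFHD1 and IFT70B lay above that on both. SLC2A10, a glucose transporter of the facilitative family, was at least 13.6-fold lower, IFT70B at least 9.74-fold and LOC101926959 at least 2.13-fold. Fold changes were taken on log2(value + 16), which understates changes of dim genes.

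**Figure D1:**
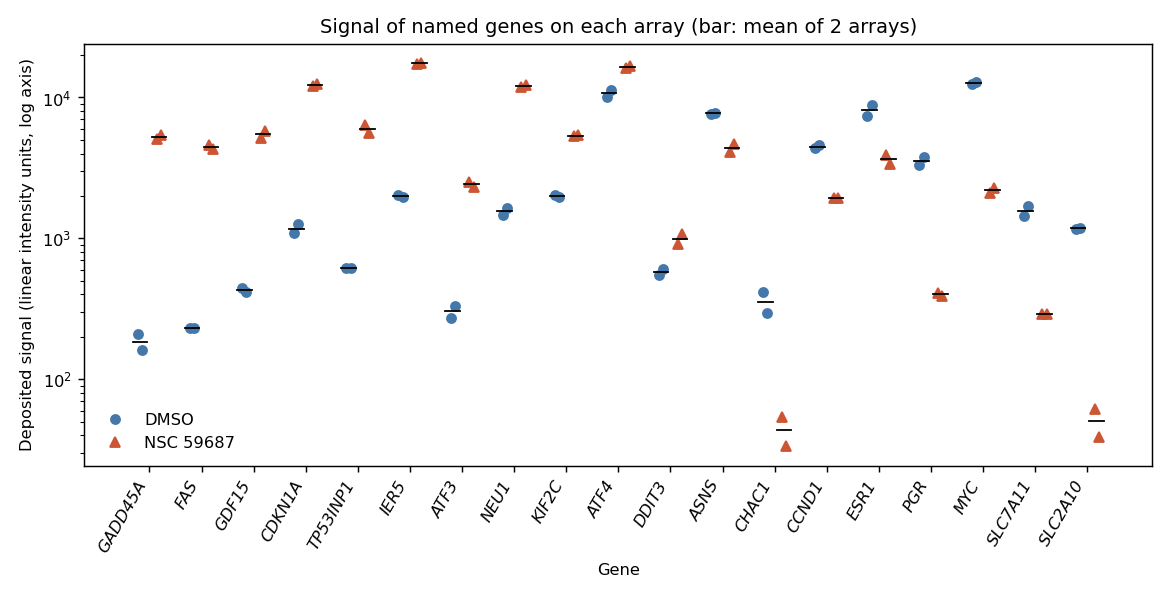
Deposited signal in linear intensity units on a log axis for 19 named genes, with circles for the 2 DMSO arrays, triangles for the 2 NSC 59687 arrays and a bar at each mean. GADD45A lies at 184 on average in DMSO and 5209 in NSC 59687, and MYC lies at 12728 and 2197.

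Of 20 measured p53 target genes, 16 rose and 0 fell, and 17 rose when adjusted over the list alone. The median log2 fold change of the list was 1.84 as deposited, 1.87 after quantile normalization and 2.20 after median centring. TP53INP1, a p53-induced gene also tied to autophagy, rose by 3.24 ± 0.14 on the log2 scale, 9.48-fold. In camera, which compares a list with all other genes, the list shifted upward (adjusted p = 2.24e-14, and adjusted p = 0.355 with an estimated correlation). With the trended spread and DMSO replicate 2 left out, 17 members rose and 0 fell.

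Of 23 measured apoptosis and death receptor genes, 7 rose and 1 fell, or 10 and 2 adjusted over the list alone. The receptors for the death ligand TRAIL rose, TNFRSF10A by 2.06 ± 0.18 and TNFRSF10B by 1.87 ± 0.14. BCL2, which restrains apoptosis, fell from 3897 ± 104 to 712 ± 107, a 5.40-fold difference. FAS, the largest rise here, is also among the p53 targets, so these lists are not independent. The apoptosis list shifted upward in camera (adjusted p = 0.00117, and adjusted p = 0.355 with an estimated correlation). Without DMSO replicate 2 and with the trended spread, 11 members rose and 2 fell.

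Of 35 measured G2/M and mitosis genes, 19 rose and 0 fell, with 24 rises adjusted over the list alone and 14 after quantile normalization. KIF2C, a kinesin that removes tubulin from microtubule ends, rose from 1999 ± 56.5 to 5354 ± 62.9. CENPE, a kinetochore motor, rose 2.38-fold. MKI67, the proliferation marker Ki-67, rose 2.30-fold, a call that ended when its probe sets were averaged and its log2 fold change became 0.25. CDK1 rose 2.35-fold, a log2 fold change of 1.23. Its call ended after quantile normalization (1.19, adjusted p = 0.0547), with a pseudocount of 1 (1.23, adjusted p = 0.0668) and with shared probe sets left out (1.23, adjusted p = 0.0508), so the change kept its size. The list's median log2 fold change was 0.70, and camera placed it above other genes (adjusted p = 3.62e-12, and adjusted p = 0.355 with an estimated correlation). Leaving out DMSO replicate 2 with the trended spread gave 26 rises and 0 falls.

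Of 33 measured G1/S and DNA replication genes, 1 rose and 7 fell, or 1 and 10 adjusted over the list alone, and after median centring 3 rose and 3 fell. PRIM1, the catalytic primase subunit, fell from 3487 ± 48.1 to 1023 ± 45.2. POLA1, the DNA polymerase alpha subunit, fell 2.30-fold. CCND1, which encodes cyclin D1, fell from 4469.5 ± 156 to 1941 ± 11.8 (log2 fold change −1.20 ± 0.13, adjusted p = 0.0189), a call that ended when its probe sets were averaged (−0.38). CDC25A, a phosphatase that activates cyclin-dependent kinases, rose 2.11-fold, a call that ended with a pseudocount of 1 (log2 fold change 1.08, then 1.11 with adjusted p = 0.0596). The list as a whole was not called (adjusted p = 0.293), and its median of −0.30 turned to 0.06 after median centring. It was called downward after quantile normalization (adjusted p = 0.0192) and without DMSO replicate 2 with the trended spread (adjusted p = 0.0420).

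Of 10 measured replication-dependent histone genes, 6 rose and 0 fell, with 7 rises adjusted over the list alone. The linker histone H1-2 rose from 409 ± 19.9 to 2115 ± 210.2, and the core histone H4C8 rose 4.76-fold. H2BC21 rose 2.76-fold and H2BC4 rose 1.88-fold. The list's median was 0.77, above other genes in camera (adjusted p = 3.77e-06, and adjusted p = 0.355 with an estimated correlation). With DMSO replicate 2 left out and the trended spread, 8 members rose and 0 fell.

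Of 26 measured estrogen-responsive genes, 1 rose and 15 fell, or 1 and 17 adjusted over the list alone. PGR fell 8.57-fold. EGR3, an immediate early transcription factor, fell 4.72-fold, and MYB, a transcription factor, fell 4.59-fold. FHL2, a LIM domain cofactor, rose 4.19-fold. ESR1, the estrogen receptor itself, fell from 8115 ± 1002 to 3652 ± 361 (log2 fold change −1.15 ± 0.17, adjusted p = 0.0277), a call that ended after median centring (−0.79, adjusted p = 0.0557) and when its probe sets were averaged (−0.82, adjusted p = 0.0528). The list's median was −1.08, below other genes in camera (adjusted p = 0.000314, and adjusted p = 0.431 with an estimated correlation). After median centring 11 members fell, and without DMSO replicate 2 and with the trended spread 18 fell.

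Of 19 luminal epithelial markers, 0 rose and 7 fell, with 1 rise and 7 falls adjusted over the list alone and 1 and 3 after median centring. SPDEF, a luminal transcription factor, fell 6.05-fold, and XBP1, a transcription factor of the unfolded protein response, fell from 17680.0 ± 4332 to 4084 ± 100.3. MUC1, an epithelial mucin, fell 2.49-fold. The list's median was −0.60, and it was not called by camera as deposited (adjusted p = 0.228). After quantile normalization it was called downward (adjusted p = 0.0272), as it was with the trended spread without DMSO replicate 1 (adjusted p = 0.00677) or DMSO replicate 2 (adjusted p = 0.0420). Of 14 basal and mesenchymal markers, 2 rose and 4 fell, also adjusted over the list alone, and 1 fell after median centring or quantile normalization. ZEB1, a repressor of epithelial genes, rose from 11.95 ± 1.23, within the control range, to 128 ± 4.92, at least 1.64-fold. Its call ended with shared probe sets left out (log2 fold change 2.37, then 2.02 with adjusted p = 0.0528). The adhesion receptor CD44 fell 3.70-fold. That list was not called (adjusted p = 0.978), with a median of −0.39 below 0 and a camera direction upward.

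Of 24 measured regulators of the integrated stress response, which is driven by eIF2 phosphorylation, 8 rose and 8 fell, or 9 and 10 adjusted over the list alone. After median centring 9 rose and 4 fell. ATF3, a stress-induced transcription factor, rose from 303 ± 41.2 to 2431 ± 142 (log2 fold change 2.94 ± 0.17, adjusted p = 0.0177). CREBRF, a regulator of CREB3 proteins, rose 6.31-fold. DDIT3, which encodes CHOP, rose 1.71-fold (log2 fold change 0.77, adjusted p = 0.0474). Its call ended with a pseudocount of 1 (0.79, adjusted p = 0.0695) and with shared probe sets left out (0.77, adjusted p = 0.0599), and the change kept its size. CHAC1, a glutathione-degrading enzyme and a target of ATF4, fell from 355.5 ± 81.6 to 43.9 ± 14.8, within the control range, at least 4.18-fold lower (adjusted p = 0.0186). ATF4 itself had a log2 fold change of 0.63 ± 0.14 and was not called (adjusted p = 0.0560), though it was called after median centring, with dim genes left out, with the trended spread and with a pseudocount of 64. TRIB3, another target of ATF4, had −0.94 ± 0.25 and was not called (adjusted p = 0.0759), though it was called in these settings other than median centring and when its probe sets were averaged. The list was not called by camera (adjusted p = 0.293), but fry, which asks whether members move one way on balance, called it upward (adjusted p = 0.0150). Its median of −0.13 differed in sign from its mean of 0.11 and from the camera direction, and it turned to 0.09 after quantile normalization and 0.22 after median centring.

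Of 25 measured genes that make and import amino acids, 2 rose and 14 fell, or 3 and 16 adjusted over the list alone. The cystine transporter SLC7A11 fell from 1576 ± 185 to 291 ± 2.38. CBS, of the transsulfuration pathway, fell 3.65-fold, and the serine synthesis enzymes PSAT1 and PSPH fell 3.10-fold and 3.05-fold. ASNS, asparagine synthetase, fell from 7702 ± 110.3 to 4401 ± 390.2 (log2 fold change −0.81 ± 0.14, adjusted p = 0.0356). Its call ended after median centring (−0.45, adjusted p = 0.136), with shared probe sets left out (−1.09, adjusted p = 0.145) and with a pseudocount of 1 (−0.81, adjusted p = 0.0562). The list was below other genes in camera (adjusted p = 0.0388, and adjusted p = 0.551 with an estimated correlation), and 8 members fell after median centring. Of 17 cytosolic tRNA synthetases, 0 rose and 6 fell, with 7 falls adjusted over the list alone and 2 after median centring. EPRS1 fell 2.55-fold and LARS1 fell 2.47-fold. That list was also below other genes (adjusted p = 0.0258, and adjusted p = 0.551 with an estimated correlation), a call that ended after median centring (adjusted p = 0.153). Both calls ended when probe sets were averaged (adjusted p = 0.0661 and 0.183) and with shared probe sets left out (adjusted p = 0.106 and 0.0722). With each array left out in turn, adjusted p ran from 0.0443 to 0.0918 for amino acid genes and from 0.0353 to 0.0890 for tRNA synthetases by limma's defaults, and reached at most 0.0134 and 0.00811 with the trended spread.

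Of 19 endoplasmic reticulum chaperone and degradation genes, 3 rose and 1 fell, or 3 and 3 adjusted over the list alone and 5 and 1 after median centring. The co-chaperone DNAJB9 rose 2.11-fold, a call that ended with shared probe sets left out (log2 fold change 1.08, then 0.66). HSPA5, which encodes the chaperone BiP, rose from 10321 ± 853 to 16905 ± 652, a log2 fold change of 0.71, but the mean of its probe sets gave −0.19. Its call also ended with a pseudocount of 1 (0.71, adjusted p = 0.0661), with shared probe sets left out (0.71, adjusted p = 0.0578) and with the trended spread without NSC 59687 replicate 1 (0.67, adjusted p = 0.0559). The list was not called (adjusted p = 0.403), and its median of −0.01, mean of −0.12 and upward camera direction differed in sign. The median was −0.10 after quantile normalization and 0.35 after median centring.

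Of 29 autophagy genes, 7 rose and 4 fell, or 12 and 6 adjusted over the list alone. Quantile normalization gave 7 and 2, and median centring 13 and 1. UVRAG, a partner of beclin, rose 3.73-fold, and MAP1LC3B, which encodes the autophagosome protein LC3B, rose from 3163 ± 244 to 9861 ± 365. BNIP3, a mitophagy receptor, fell 3.73-fold. The cargo receptor SQSTM1 had a log2 fold change of 0.62 ± 0.14 and was not called (adjusted p = 0.0562), though it was called after median centring, with dim genes left out, with the trended spread and with a pseudocount of 64. The list was above other genes in camera (adjusted p = 0.000436, and adjusted p = 0.355 with an estimated correlation). Its largest rise, TP53INP1, is also among the p53 targets. Of 21 lysosome genes, 6 rose and 0 fell, with 8 rises adjusted over the list alone, 4 after quantile normalization and 10 after median centring. NEU1, lysosomal sialidase, rose from 1553 ± 109 to 12102 ± 323. NPC1, a cholesterol exporter of the lysosome, rose 2.05-fold, a call that ended when its probe sets were averaged (log2 fold change 1.04, then 0.28). That list was also above other genes (adjusted p = 0.000314, and adjusted p = 0.355 with an estimated correlation). Without DMSO replicate 2 and with the trended spread, 9 autophagy genes rose and 6 fell, and 9 lysosome genes rose and 0 fell.

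Of 25 genes of the eIF2 kinases and the mTOR pathway, 6 rose and 8 fell, or 7 and 10 adjusted over the list alone. LAMTOR3, a scaffold of mTORC1 at the lysosome, rose 3.26-fold, and PRKAB1, a subunit of the energy sensor AMPK, rose 3.42-fold. The mTOR inhibitor DEPTOR fell 2.54-fold, a call that ended when its probe sets were averaged (log2 fold change −1.35, then −0.65). NPRL2, a subunit of the GATOR1 complex, fell 3.65-fold (log2 fold change −1.87), but gave 1.04 with shared probe sets left out and −0.42 with its probe sets averaged, where it was not called. The list was not called by camera (adjusted p = 0.865), whose direction was upward while the median was −0.34 and the mean −0.17. The median was 0.01 after median centring. Fry, which does not compare the list with other genes, gave a downward direction (adjusted p = 0.0109). After median centring 6 members rose and 4 fell.

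Of 22 immediate early genes, which respond to stimuli within minutes, 10 rose and 5 fell, or 10 and 6 adjusted over the list alone and 11 and 3 after median centring. IER5 rose from 2001 ± 35.1 to 17448 ± 98.1, and the orphan nuclear receptor NR4A3 rose from 6.60 ± 1.29, within the control range, to 129 ± 28.3, at least 1.64-fold, a call that ended with a pseudocount of 1 (adjusted p = 0.497) and with shared probe sets left out (adjusted p = 0.503). MYC fell 5.76-fold. The list was above other genes in camera (adjusted p = 0.00292, and adjusted p = 0.355 with an estimated correlation), a call that ended when dim genes were left out (adjusted p = 0.159). Of 25 TNF and NF-κB targets, 2 rose and 2 fell, also adjusted over the list alone, and after median centring 3 rose and 1 fell. IER3, an early stress response gene, fell 2.96-fold, and NFKBIE, an inhibitor of NF-κB, rose 1.87-fold. TNF had a signal of 37.7 ± 14.9 in DMSO and 66.0 ± 8.98 in NSC 59687, means within the control range, and was not called (adjusted p = 0.163). The list was not called (adjusted p = 0.325), and its median of −0.11, opposite to its camera direction, turned to 0.23 after quantile normalization and 0.25 after median centring.

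Of 28 hypoxia and glycolysis genes, 2 rose and 9 fell, or 2 and 16 adjusted over the list alone, and 6 fell after median centring. PFKP, a phosphofructokinase, fell from 4413 ± 625 to 898 ± 71.7. HK2, a hexokinase, fell 4.25-fold, and PFKFB4, which makes an activator of phosphofructokinase, fell 4.30-fold, a call that ended when its probe sets were averaged (log2 fold change −2.10, then −1.34 with adjusted p = 0.0804). The hormone precursor ADM rose from 28.0 ± 25.4, within the control range, to 206 ± 24.9, at least 2.52-fold (fitted log2 fold change 2.46). Its call ended with a pseudocount of 1 (3.18, adjusted p = 0.0924) and with the trended spread without NSC 59687 replicate 2 (2.35). Of 14 fatty acid synthesis genes, 0 rose and 4 fell, with 5 falls adjusted over the list alone and 2 after median centring. ELOVL6, a fatty acid elongase, fell 2.82-fold, and ACLY, which makes cytosolic acetyl-CoA, fell 2.43-fold. Camera placed both lists below other genes (adjusted p = 0.0362 for hypoxia and glycolysis and 0.0388 for fatty acid synthesis). With an estimated correlation these became adjusted p = 0.674 and adjusted p = 0.551. The call of fatty acid synthesis ended after median centring (adjusted p = 0.136), when probe sets were averaged (adjusted p = 0.622) and with shared probe sets left out (adjusted p = 0.364). With each array left out in turn, adjusted p ran from 0.0421 to 0.1002 for hypoxia and glycolysis and from 0.0443 to 0.0918 for fatty acid synthesis by the defaults, and reached at most 0.0289 and 0.0207 with the trended spread. Of 18 cholesterol synthesis genes, 1 rose and 6 fell, or 2 and 10 adjusted over the list alone, and after median centring 3 rose and 2 fell. SQLE, squalene epoxidase, fell 2.38-fold, and SC5D, a sterol desaturase, rose 4.06-fold (log2 fold change 2.02), a call that ended when its probe sets were averaged (1.66, adjusted p = 0.0987) and with shared probe sets left out (1.31, adjusted p = 0.427). That list was not called (adjusted p = 0.748). Its members HMGCR, FDFT1, CYP51A1, DHCR24, LDLR and PCSK9 were not measured in the gene test.

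Of 24 ribosome biogenesis genes, 1 rose and 7 fell, or 1 and 9 adjusted over the list alone, and 2 fell after median centring. POLR1B, a subunit of RNA polymerase I, fell from 2327 ± 24.0 to 742 ± 3.03, and MYC is also in this list. The list was below other genes in camera (adjusted p = 0.0390, and adjusted p = 0.431 with an estimated correlation). The call ended after median centring (adjusted p = 0.127) and with shared probe sets left out (adjusted p = 0.0552). It also ended by the defaults with any array left out (adjusted p from 0.0623 to 0.101), but adjusted p was at most 0.0109 in these fits with the trended spread. Of 31 cytosolic ribosomal protein genes, 0 rose and 0 fell by limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. The brightest, RPS23, had a signal of 48995 ± 16569 in DMSO and 38412 ± 1148 in NSC 59687. The list was not called (adjusted p = 0.387), and its median of −0.31 turned to 0.05 after median centring. It was called downward without DMSO replicate 1 (adjusted p = 0.000573) but not without DMSO replicate 2 (adjusted p = 0.396) or either NSC 59687 array (adjusted p = 0.802 and 0.446). RPS23 had a log2 fold change of −0.31, which was −0.66 without DMSO replicate 1 and 0.04 without DMSO replicate 2. Of 26 translation factors, 1 rose and 3 fell, and 0 did so adjusted over the list alone, while 3 rose and 0 fell after median centring. EIF4B, an initiation factor, fell 1.90-fold, a call that ended after median centring (log2 fold change −0.93, then −0.57). EIF5 rose 1.61-fold (log2 fold change 0.69), but gave −0.14 with shared probe sets left out. Its call also ended with its probe sets averaged (0.56, adjusted p = 0.0602), with a pseudocount of 1 (0.69, adjusted p = 0.0638) and after quantile normalization (0.61, adjusted p = 0.0507). The list was not called (adjusted p = 0.978), with a median of −0.15 against an upward camera direction, and a median of 0.21 after median centring.

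The remaining lists were not called by camera as deposited. Of the lists camera did not call, fry called G1/S, luminal, heat shock, interferon, oxidative stress and xenobiotic genes downward (adjusted p from 0.00441 to 0.0315). Fry tests a list against 0 and not against other genes. It was run only as deposited, where the median of all genes was −0.26. The medians of the oxidative stress and G1/S lists differed from that by only −0.004 and −0.05, so their calls may reflect the shift of all genes. Of 33 oxidative phosphorylation genes, 0 rose and 1 fell, with 0 adjusted over the list alone (adjusted p = 0.252). Their median was 0.03, their mean was −0.03 and the list was called upward after median centring (adjusted p = 0.0172) and with the trended spread without DMSO replicate 2 (adjusted p = 0.0404). Of 21 genes of mitochondrial stress and biogenesis, 1 rose and 1 fell, with 0 adjusted over the list alone (adjusted p = 0.966). DNM1L, of mitochondrial fission, fell 1.58-fold (log2 fold change −0.66), but the mean of its probe sets gave 0.13. Its call also ended after median centring (−0.30, adjusted p = 0.264), with a pseudocount of 1 (−0.66, adjusted p = 0.0628) and with shared probe sets left out (−0.66, adjusted p = 0.0574). Of 21 oxidative stress and glutathione genes, 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (adjusted p = 0.978). After median centring 3 rose and 1 fell in this list, and the medians of the last pair of lists, both −0.26, turned to 0.10. Of 17 measured heat shock genes, 1 rose and 5 fell, or 2 and 8 adjusted over the list alone. Their median was −0.54 (camera adjusted p = 0.359), and after median centring 2 rose and 0 fell. The listed heat shock genes HSPA1A, HSPA1B and HSPA8 were not measured in the gene test. Of 23 interferon-stimulated genes, 0 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.293), and 1 fell after quantile normalization, or 1 rose and 2 fell after median centring. Of 18 xenobiotic metabolism genes, 2 rose and 2 fell, or 2 and 5 adjusted over the list alone (adjusted p = 0.806), and 1 fell after median centring. CYP1A1 and TIPARP, which is also induced through the aryl hydrocarbon receptor, were the pair that rose, and the sulfotransferase SULT1A1 fell 3.40-fold. Of 10 metallothionein and zinc transport genes, 0 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.806), and the median of −0.16 turned to 0.20 after median centring. The gene that fell was SLC39A10, a zinc importer, by 3.17-fold.

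Of 12 fibroblast markers, 0 were called by limma, also adjusted over the list alone, and 5 had an unadjusted p under 0.05 (list adjusted p = 0.252). COL1A1 had a signal of 887 ± 35.6 in DMSO and 616 ± 6.55 in NSC 59687 (adjusted p = 0.0686), and was called downward with dim genes left out (adjusted p = 0.00781), with the trended spread (adjusted p = 0.0146, or 0.0367 without DMSO replicate 1) and with a pseudocount of 64 (adjusted p = 0.0333). Of 12 leukocyte markers, 1 rose and 2 fell, also adjusted over the list alone, with a list adjusted p of 0.325, and after median centring 1 rose and 0 fell. The called markers were CD14, ITGAM and CD2, whose mean signals were at most 118 in either group, and CD14 lay within the control range in both. Each of these calls ended in at least 1 other setting.

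**Figure D2:**
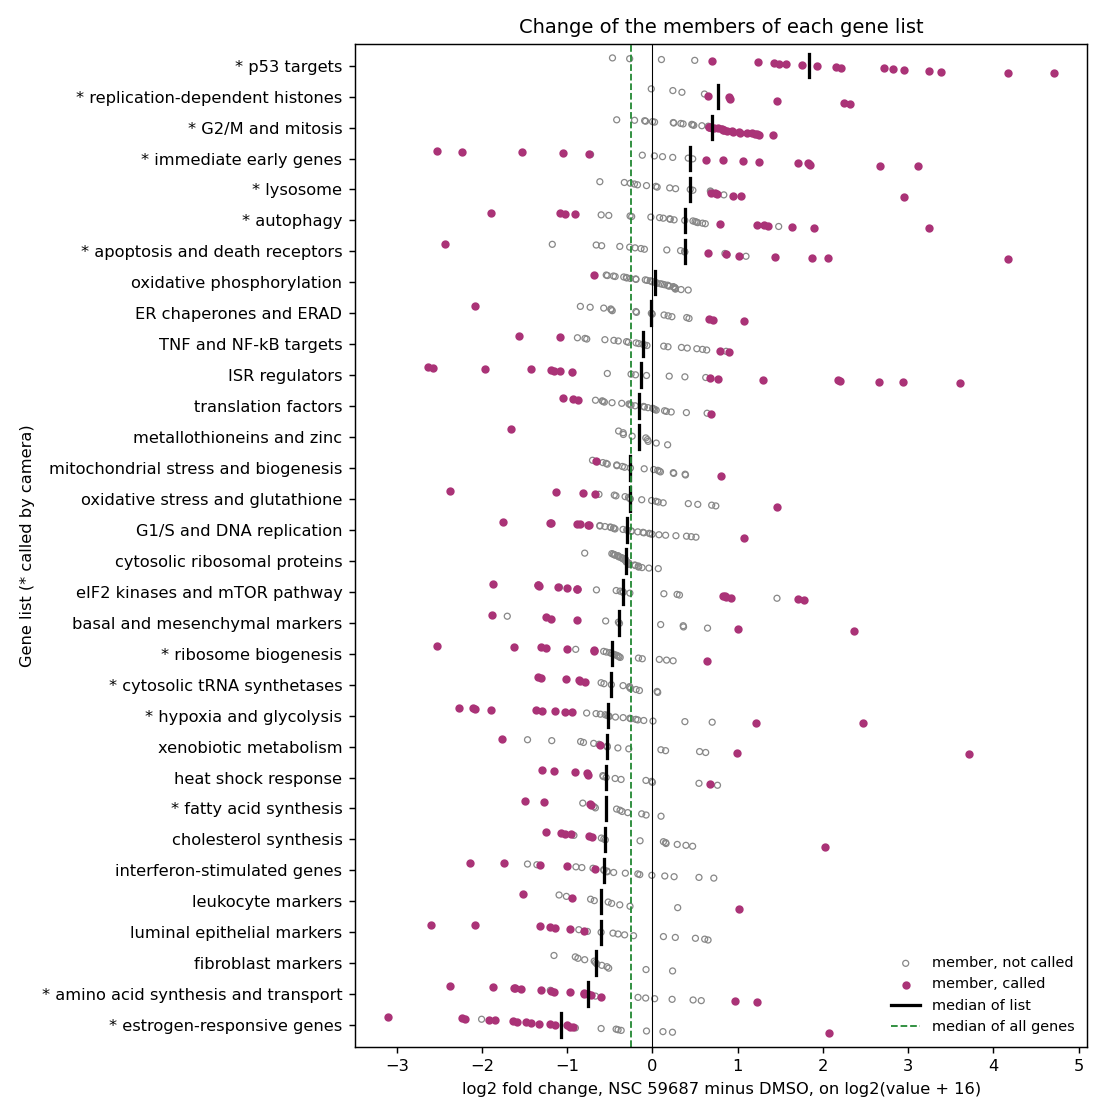
Log2 fold change (NSC 59687 minus DMSO, on log2(value + 16)) of each member of the 32 gene lists, with filled points for called members, open points for others, a black bar at each list's median and a star before the lists called by camera. The p53 targets have the highest median, 1.84, and the estrogen-responsive genes the lowest, −1.08, while the median of all genes is −0.26.

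The size of the change depended on signal level. With genes in 10 bins of rising mean signal, bins 5 and 6 had median log2 fold changes of −0.51 and −0.52, and the brightest bin had 0.07. Without DMSO replicate 2 these medians were −0.45, −0.51 and 0.11. Quantile normalization left −0.16, −0.23 and 0.01.

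**Figure D3:**
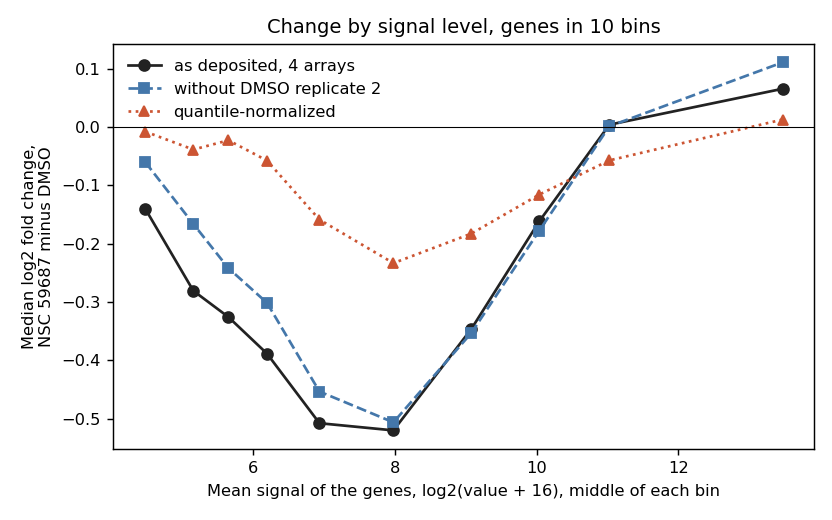
Median log2 fold change (NSC 59687 minus DMSO) of genes in 10 bins of mean signal on log2(value + 16), as deposited, without DMSO replicate 2 and after quantile normalization. The lowest point as deposited is −0.52, in the sixth bin, and the line crosses 0 near the brightest genes.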

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

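Each result here was seen in data outside the comparison of named genes, and none was explained by a test. Probe sets with no gene symbol, or with several, were tested together with all others by limma, and 299 of them rose and 680 fell out of 13522. The largest fitted rises were in probe set 233413_at, from a mean signal of 27.0 in DMSO to 1633 in NSC 59687, and in 240964_at, from 60.8 to 1880. The largest fitted falls were in 207302_at, from 596 to 24.0, and in 239991_at, from 244 to 8.19. In each of these 4 the dimmer group's mean lay within the range of trpn control probe sets, 3.81 to 71.8, so their order and exact folds are not set. The added hybridisation controls were 2.28 times as bright on DMSO replicate 2 as on DMSO replicate 1, by the median over 9 probe sets, and 1.79 times the mean of the NSC 59687 arrays.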

How the results depend on the processing

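The leave-one-out fits with trended spread were chosen after seeing the data; the other settings were planned. With each array left out and limma's defaults, 0 genes were called upward, downward or in all (5368 to 7212 at an unadjusted p under 0.05), since 1 residual degree of freedom remains and the lone array is assumed to vary like the other group. Camera called 8 to 13 lists in these fits. With trended spread they called 4252 to 5985 genes, 1475 to 2160 upward and 2777 to 3880 downward, 2465 to 3040 at least 2-fold, and 13 to 16 lists. The replicate block also called 0 genes, at any fold or direction, with 6747 at an unadjusted p under 0.05, and 8 lists. Deviations of same-numbered arrays correlated at −0.00793, which gives no sign of pairing. A threshold of 0.01 gave 0 genes in either direction, because the lowest adjusted p was 0.0177, and a threshold of 0.1 gave 6802, 2161 upward and 4641 downward. Median centring gave 2366 rises and 1306 falls. Trended and robust spread called 6571 genes with 2356 rises, and leaving out dim genes gave 2405 rises. Leaving out probe sets with shared probes called 2829 genes with 852 rises. A pseudocount of 1 called 2748 genes, 865 upward and 1883 downward. Testing every probe set called 5358 at least 2-fold. With an estimated correlation, where each list is judged on the few residual degrees of freedom, camera called 0 lists (13 with the preset one). Fry called 21. Averaging probe sets gave 10 called lists and leaving out shared ones 9. Of the 4331 genes, 4254 kept their sign with probe sets averaged (77 did not), 4324 with a pseudocount of 1, 4330 with quantile normalization or a pseudocount of 64 and 4331 with median centring. Of the 3710 still measured without shared probe sets, 3511 did and 199 did not. Among the 134 named genes, averaging reversed HSPA5 (−0.19) and DNM1L (0.13), and leaving out shared probe sets reversed GDF15 (−1.03), EIF5 (−0.14) and NPRL2 (1.04), through another probe set of each gene. Named genes with only shared probe sets, CDKN1A and MYC among them, were not tested with those left out. Fry turned the direction of the eIF2 kinase and mTOR list (adjusted p = 0.0109). For the other changes the cause was not tested. Bacterial trpn control probe sets, which should not hybridise, read 3.81 to 71.8, so genes in that range are near background.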

Other observations

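The tests of a wider set of histone genes, of antisense RNAs and of list medians against random lists were chosen after seeing the main results. The tests on added control transcripts, on DMSO replicate 1 alone and on the G1/S list were chosen after their values had been seen. Including members of the fixed list, 41 genes of the clustered histone families were measured. Of these, 14 rose and 0 fell, and their median log2 fold change was 0.61, against a median of −0.33 for random gene lists of the same size and signal. Genes named as antisense RNAs fell more often than they rose, with 15 rises and 107 falls among 792. The hypothesis that antisense RNAs fell more than other genes of like signal was not borne out. Their median of −0.32 lay at the 43.02nd percentile of 10000 random lists matched on signal.

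Genes of middling signal had a median log2 fold change of −0.46 over 5932 genes in bins 5 to 7 of 10. A background or response difference between arrays is a candidate explanation. The 13 added Bacillus control probe sets in the same signal range changed by a median of −0.13, with values from −0.23 to 0.39. None fell as far as the genes' median. These probe sets read only 4 transcripts, whose medians ran from −0.16 to 0.39, so a standard error over probe sets (0.0453) is too small. The values cannot decide how far such a difference contributes, and the labels do not say how the transcripts were added. A fault of DMSO replicate 2 alone is another candidate explanation. Against DMSO replicate 1 alone the median was −0.44, which argues against that array as the cause. A background or response difference stays open. A change in total RNA per cell, which scaling to a common mean hides, and an effect of the compound stay open and untested.

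The lists that moved may have done so through the signal level of the list, because genes of middling signal fell while the brightest bin had a median of 0.07. Of the lists that shifted upward, 7 of 7 had medians above the central 95% of random lists matched on signal, and of those that shifted downward, 6 of 6 lay below it. Independently drawn genes of like signal thus seldom gave medians this far out in either direction. These lists had been picked by camera's calls on the same arrays, and real members can vary together. The counts are therefore not independent support for the calls. Luminal markers, heat shock genes, cytosolic ribosomal proteins, cholesterol synthesis and G1/S genes, none of them called by camera, also lay below the central 95%. An effect of the compound is a hypothesis that remains, and so does any sample difference that runs with the groups.

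Of the 41 histone genes 14 were called upward. Camera's call of the fixed list was lost with an estimated correlation (adjusted p = 0.355), as was every other list call. More cells in S phase could raise genes of DNA replication with them. The median of the G1/S and DNA replication list lay at the 2.48th percentile of random lists matched on signal, so those genes did not rise with the histone genes. That value is close to the edge of the central 95%. Transcript levels of these genes do not measure the share of cells in S phase, so the explanation stays open. Probe sets shared between histone genes could also raise many genes at once. The 31 genes read by plain probe sets had a median of 0.61, at the 100th percentile of matched random lists, and 10 of them rose. Histone transcripts that carry poly(A) tails, which this kind of array labelling favours, were not measured separately and stay open.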
